A study of Mus musculus with 6 samples.

How the data were processed

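Liver RNA was measured by RNA sequencing in 6 libraries from C57BL/6 mice that ate a diet with 60 percent fat and received either vehicle or GUDCA (glycoursodeoxycholic acid, a glycine-conjugated bile acid) for 1 week. The labels name 3 libraries of the vehicle group, replicates 1 to 3, and 3 of the GUDCA group, replicates 4 to 6. The labels describe frozen liver, Trizol extraction and a standard Illumina library preparation. They give no sequencing batch, sex, time of collection or feeding state. The series states its group size in mice, but no label ties a library to an animal. The p-values therefore reflect the spread between these samples, which may in part be technical.

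The authors deposited 1 file of values per gene for each library, treated here as a signal and called normalized read counts in the text. Per the submitters' processing notes, the tools were HISAT2 2.1.0, StringTie 1.3.3b and featureCounts 1.5.0-p3 with genome build mm10. Their order, the scaling method, the gene annotation and the strand setting are not given in the sources used here. In each deposited file nearly all values were whole multiples of what 1 read was worth, so the counts had been divided by 1 factor per library and carried no gene length. The share of values above 0 that came out whole, within 0.01 of a read, was at least 99.9948% in every library. The recovered totals ran from 7393462 to 11753172 reads per library. A gene without a read in a library could still have held up to 3 reads' worth, which was 0.264 to 0.402 on the normalized scale. That limit covers counting error only.

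The files held 24661 genes, of which 1001 had no read in any library. Of the gene identifiers, 24652 were found in GENCODE M21, the mm10 annotation used here for symbols and coordinates, and 23972 of them carried the same version. Values were compared as log2(value + 1) for the 13700 genes with a value of at least 1 in at least 3 of the 6 libraries. Fold changes on this scale understate the change of genes with low values. The test was limma 3.58.1 in R 4.3.3 with a variance trend and Benjamini-Hochberg adjustment at 0.05, with group as the only term. All adjusted p-values of genes are from limma unless another tool is named. This test was written for normalized values before the data were examined. The count test, edgeR 4.0.16 with its quasi-likelihood test, was run on the recovered reads as an alternative, and it called 0 genes at an adjusted p of 0.05 and 1453 at an unadjusted p under 0.05. DESeq2 1.42.0 was run on the same reads as an alternative chosen after seeing the data, and it called 189 genes.

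Before the data were examined, 48 gene lists were fixed, 33 of pathways and 15 of cell type markers. The 44 lists with at least 5 measured members were tested with camera from limma at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Members were also counted after adjustment over the list alone. The rule for named genes was fixed as well. Where fewer than 5 genes passed in a direction, it took the 10 genes in that direction with the smallest unadjusted p. It added, for each list, the members that passed or otherwise the pair with the smallest p, and always the bile acid and stress genes Cyp7a1, Cyp8b1, Cyp27a1, Cyp7b1, Nr0b2, Abcb11, Hspa5 and Ddit3. Some genes that the rule takes are not described here. Other list members named in the text were chosen after their values were seen.

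The gene test and the list test were tested on simulated data, with 200 of 13488 to 13520 genes changed in each of 10 rounds drawn from the means, depths and spread of these libraries. For this comparison of 3 with 3 libraries, limma recovered 49.1% of genes changed by 1 on the log2 scale, 93.6% of those changed by 2 and 96.1% of those changed by 3. False calls made up 5.46% of its calls. A planted list was called in 10 of 10 rounds, and in 9 with an estimated correlation. Its members, the cholesterol synthesis genes, were raised by 1 on the log2 scale in addition to the 200. The simulated libraries varied independently gene by gene, so this says nothing of a library in which many genes shift together.

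The alternatives were a pseudocount of 0.1, no filter, a filter at 5, median-ratio scaling, quantile normalization, no variance trend, weights per library, and leaving out each library in turn. Others were chosen after seeing the data, namely DESeq2, edgeR with the first vehicle library left out, and the mean of the endothelial markers as a covariate. Library pairs were checked for duplicates by a chi-square of their reads over genes. The lowest value was 19.2 per gene, so no pair differed by as little as sampling noise. That pair, vehicle replicate 2 and GUDCA replicate 4, lay across the groups. The closest pair within a group, vehicle replicates 2 and 3, was at 19.7. For the named genes, the longest transcript was compared with all GENCODE M21 transcripts by BLAST 2.17.0, at 97 percent identity over at least 100 bases, to find near-identical copies. The spread of a list median in the closing section is the SD of 10000 bootstrap draws of its members. This spread treats members as independent and leaves out differences between libraries. It was added as a bound after the medians were known. No library was left out of the reported comparison.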

Results

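The transcriptome of mouse liver was profiled by RNA sequencing after 1 week of GUDCA or vehicle during feeding with a diet of 60 percent fat. GUDCA is glycoursodeoxycholic acid, the glycine conjugate of the bile acid ursodeoxycholic acid. Each group held 3 libraries. The vehicle libraries held 11753172, 10730991 and 7393462 reads in replicates 1, 2 and 3, and the GUDCA libraries 11419377, 10615215 and 9554762 in replicates 4, 5 and 6. Vehicle replicate 1 stood apart from the other libraries, at -52.8 on a first principal component that held 41.3% of the variance, while the others lay between 2.41 and 27.4. The second component held 32.0% of the variance, with vehicle replicates 2 and 3 at -22.3 and -33.6, vehicle replicate 1 at 4.41 and the GUDCA libraries between 1.64 and 27.4. Gene positions are on build mm10.

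The comparison asked which liver transcripts differ when mice on a high-fat diet receive GUDCA. Sqle, the squalene epoxidase of cholesterol synthesis, averaged 90.2 ± 24.1 normalized read counts in GUDCA livers and 21.7 ± 6.14 in vehicle livers (SD, n = 3 each). Saa3, an acute-phase serum amyloid, averaged 78.0 ± 18.6 and 10.6 ± 4.07. The clock output transcription factor Dbp averaged 47.1 ± 11.5 and 10.2 ± 4.68. In the opposite direction, the nuclear long noncoding RNA Neat1 averaged 50.5 ± 4.54 in GUDCA and 143 ± 49.4 in vehicle livers.

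These differences did not pass the test over all genes with 6 libraries. limma called 0 of 13700 genes at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 1491 genes, 777 higher and 714 lower in GUDCA. If no gene differed, 685 would be expected on average, but splits that mix the groups gave from 137 to 1411. The smallest adjusted p was 0.0517, reached by Saa3. The groups did not overlap for 16.4% of genes, against 10% on average by chance, and how far single splits lie from that average was not computed. edgeR on the recovered reads also called 0 genes, and DESeq2, chosen after seeing the data, called 189, of which 116 were higher and 73 lower. The limma count depended on single libraries. Without vehicle replicate 1 it was 55 of 13553 genes, 40 higher and 15 lower, and without GUDCA replicate 4 it was 15 genes, 13 higher and 2 lower. With any other library left out limma called 0 genes, and between 752 and 1333 genes had an unadjusted p under 0.05.

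Among the 10 genes with the smallest p in the higher direction, of which 9 are described here, the log2 fold change was 2.79 ± 0.26 (SE) for Saa3 (chromosome 7, 46711998 to 46715700, minus strand). It was 3.01 ± 0.36 for Rgs16, a regulator of G-protein signalling (adjusted p = 0.112), and 1.86 ± 0.25 for the isoprenoid enzyme Idi1 (adjusted p = 0.126). Sqle, with the means given above, had an adjusted p of 0.119. Dbp stood at 2.15, the secreted matrix protein Thbs1 at 1.61 and the collagen chain Col1a2 at 1.13, each with an adjusted p of 0.126. The set also holds antisense transcripts, Gm48342 (1.62) over Hmgcs1 and Gm28513 (2.94) over Rgs16. As the strand setting is not given, their reads cannot be told apart from those of the genes they overlap, and 29.4% of the Dbp transcript is shared with its neighbour Sphk2. Part of Idi1, 33.3% of its longest transcript, is also near-identical to sequence in other genes. All 10 were higher in every GUDCA library than in every vehicle library.

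The 10 genes with the smallest p in the lower direction were led by 1700017B05Rik, at -1.30 ± 0.16 (SE, adjusted p = 0.112), and Tbc1d30, at -1.34 ± 0.20 (adjusted p = 0.132). The linker histone gene Hist1h1c was at -1.26, the transcription factor gene Atoh8 at -0.98, the neutral sphingomyelinase gene Smpd3 at -1.40 and Neat1 at -1.43. Nedd4l, a ubiquitin ligase gene, was at -0.75, Fam222a at -2.12 and Insc at -0.98. The major urinary protein gene Mup9 was at -1.48, but its whole transcript is near-identical to other members of its family, so its value is uncertain. The adjusted p of these 10 genes ran from 0.112 to 0.167. None of their GUDCA values reached the lowest vehicle value.

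**Figure D1:**
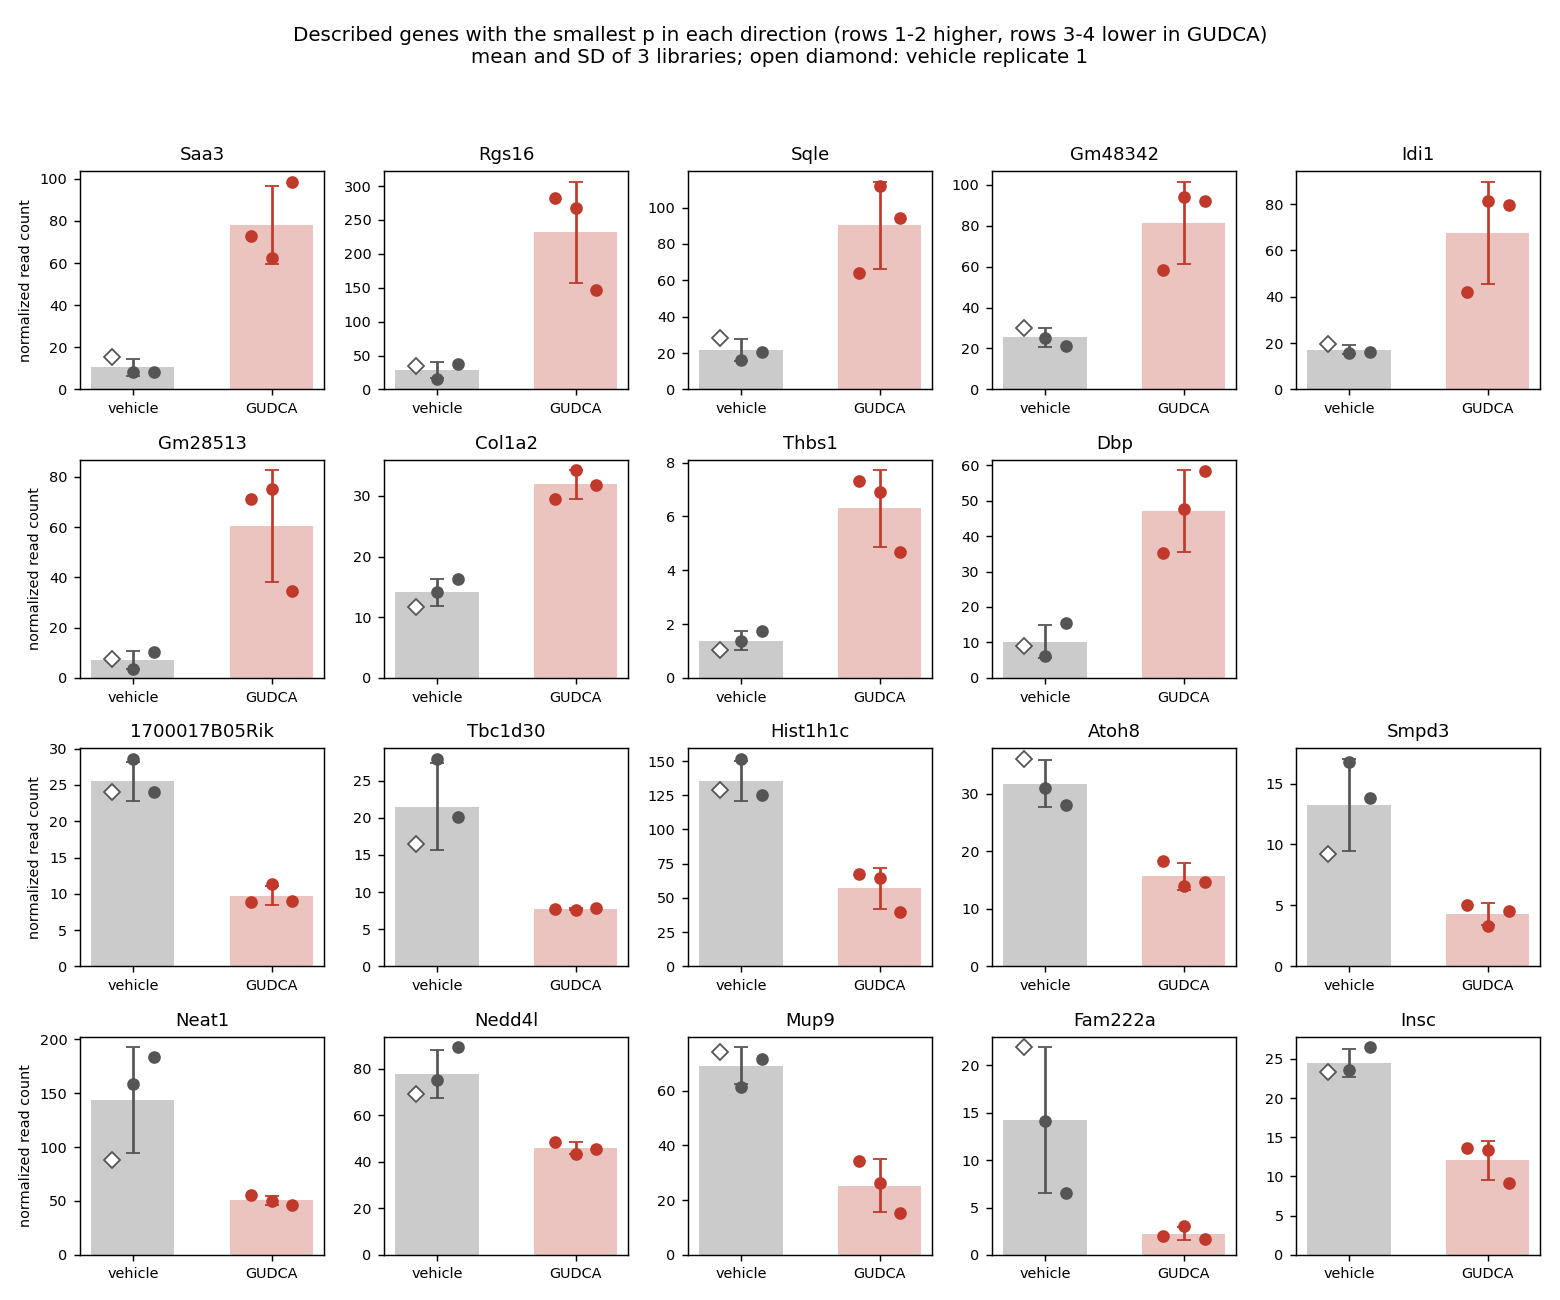
Normalized read counts of the described genes with the smallest p in each direction (9 higher and 10 lower), with 3 libraries per group (points), the mean (bars) and the SD (error bars). For Saa3 the GUDCA libraries average 78.0 and the vehicle libraries 10.6, and in each of the panels the groups do not overlap.

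With vehicle replicate 1 left out, 55 genes passed. Saa3 rose by 3.07 ± 0.19 on the log2 scale (SE, adjusted p = 0.00209), and Neat1 fell by 1.74 ± 0.13 (adjusted p = 0.0034). All 10 genes of the higher set passed in that fit. Of the lower set, 1700017B05Rik, Tbc1d30, Smpd3, Neat1 and Nedd4l passed, while Hist1h1c, Atoh8, Mup9, Fam222a and Insc did not, with adjusted p-values from 0.0609 to 0.0801. edgeR without that library called 51 genes, 49 of them among the 55. DESeq2 with 6 libraries called 39 of the 55.

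Of the 44 gene lists tested with 6 libraries, camera called 23, of which 16 were higher and 7 lower in GUDCA. With an estimated correlation it called 0, and the smallest adjusted p was 0.356. fry also called 0, with 9 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.116. Its test for change in either direction called 12 lists. Among them were lists that camera did not call, namely gluconeogenesis and glycogen, insulin signalling and the acute phase response. Apoptosis and p53 targets and the markers of intestine, gallbladder and mesothelium were others. Below, a list is named as called or not called by camera unless fry is named. Without vehicle replicate 1, camera called 15 lists, all of them among the 23 and in the same direction, and 0 with an estimated correlation, where the smallest adjusted p was 0.511. Splits of the 6 libraries that mix the groups gave 12 to 22 called lists, so a call at the preset correlation is a weak statement by itself. In no list did a member pass over all genes with 6 libraries in limma, and counts of members given as adjusted over the list alone stand beside that.

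**Figure D2:**
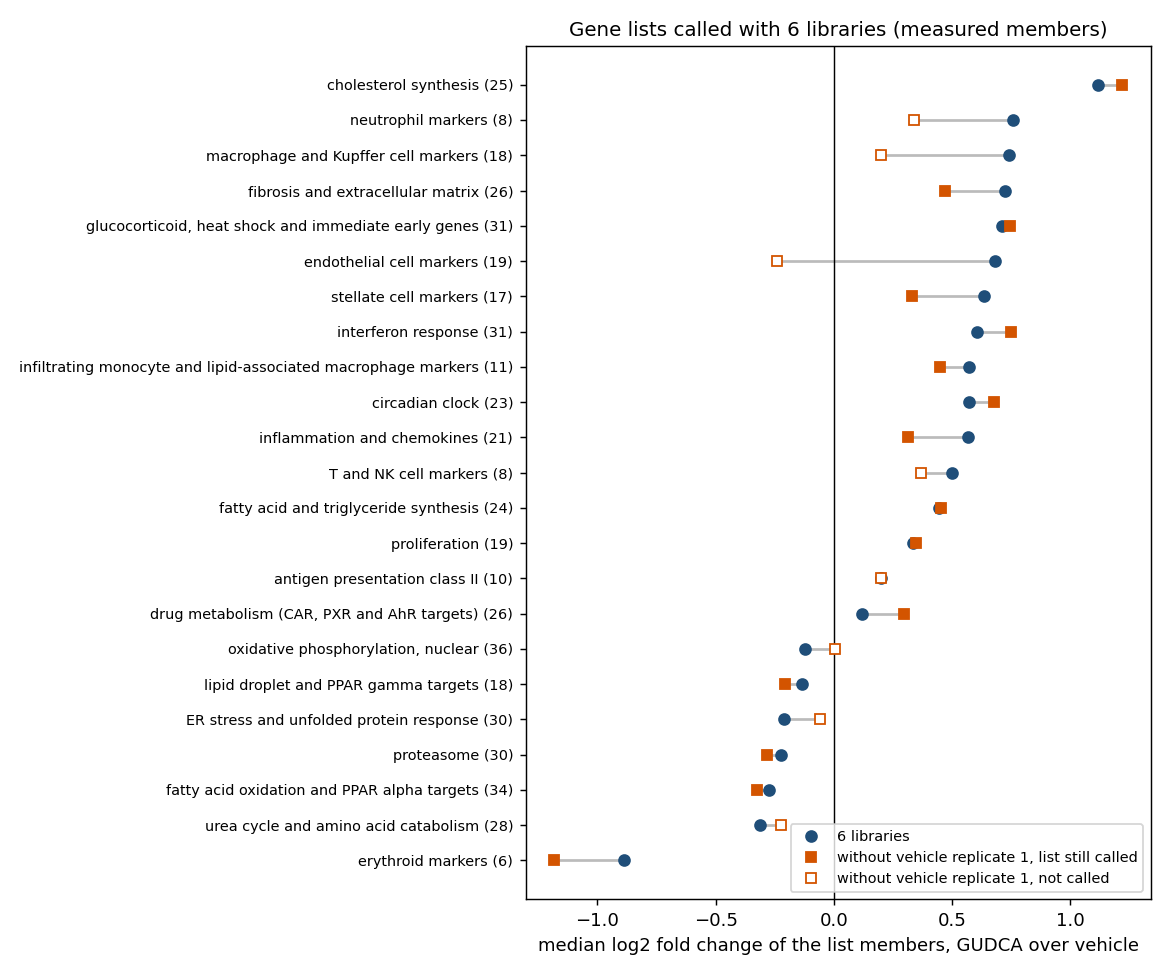
Median log2 fold change, GUDCA over vehicle, of the members of the 23 lists called with 6 libraries (circles) and the same lists without vehicle replicate 1 (squares, filled where the list was still called). Cholesterol synthesis moved from 1.12 to 1.22, and the endothelial markers moved from 0.68 to -0.24.

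Cholesterol synthesis genes rose together in GUDCA livers. The median log2 fold change of the 25 measured members was 1.12 (camera adjusted p = 4.57e-22, and adjusted p = 0.403 with an estimated correlation). Adjusted over the list alone, 20 members rose, 0 fell and 5 did not pass, and 20 had an unadjusted p under 0.05. The synthase gene Hmgcs1 averaged 246 ± 59.8 in GUDCA and 80.3 ± 25.0 in vehicle livers (SD, n = 3 each), and Mvd, of the mevalonate pathway, 19.8 ± 6.58 and 3.79 ± 2.05. Without vehicle replicate 1, which lay 0.52 above the other vehicle libraries in this list, the median was 1.22 and 13 members passed over all genes, among them Sqle, Idi1, Mvd and Insig1. The wider list of lipoprotein assembly and cholesterol handling was not called (24 members, median 0.024, adjusted p = 0.906), and 0 members passed adjusted over the list alone, with 3 at an unadjusted p under 0.05. In it the apolipoprotein gene Apoa5 was at -0.57, and 27.0% of the Apoa5 transcript is shared with Gm47544, an antisense gene that overlaps it. Adjusted over that list alone, 3 members rose and 1 fell without vehicle replicate 1, where the median was 0.042.

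The list of fatty acid and triglyceride synthesis was also called higher, with a median of 0.45 over 24 members (camera adjusted p = 0.00135, and adjusted p = 0.409 with an estimated correlation). Of its members 2 rose, 0 fell and 22 did not pass adjusted over the list alone. Those that rose were Aacs, which makes acetoacetyl-CoA in the cytosol, at 2.59 ± 0.38 (SE), and the fatty acid synthase gene Fasn, at 151 ± 41.0 in GUDCA and 54.9 ± 25.0 in vehicle livers (SD, n = 3 each). Vehicle replicate 1 lay 0.30 above the other vehicle libraries in this list, and without it 10 members rose and 3 fell adjusted over the list alone, and 3 passed over all genes. The third was the desaturase Scd1, at 3.02 (adjusted p = 0.0126) without that library and 1.89 (adjusted p = 0.473) with it. Elovl5 and Agpat2 went the other way, at -0.99 and -0.49 with unadjusted p-values of 0.0245 and 0.0456.

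Circadian clock genes were called higher as a list, with members in both directions. The median of 23 members was 0.57 (camera adjusted p = 4.08e-07, and adjusted p = 0.356 with an estimated correlation). Adjusted over the list alone, 11 rose, 2 fell and 10 did not pass. Dbp and Wee1 were at 2.15 and 1.45, the period genes Per2 and Per3 at 1.21 and 1.59, and Tef at 1.09. Those that fell were Arntl, the gene of the activator BMAL1, at -1.39 ± 0.38 (SE), and its partner gene Npas2 at -0.98 ± 0.30. Without vehicle replicate 1 the median was 0.68, and Dbp and Noct passed over all genes. Noct was at 1.62 against 1.05 with 6 libraries, though 47.8% of its longest transcript is shared with other genes, so its value is uncertain. Npas2, which averaged only 0.53 in GUDCA and 2.12 in vehicle livers, did not pass the filter without that library. Of the 22 members measured in that fit, 14 rose and 2 fell adjusted over the list alone.

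**Figure D3:**
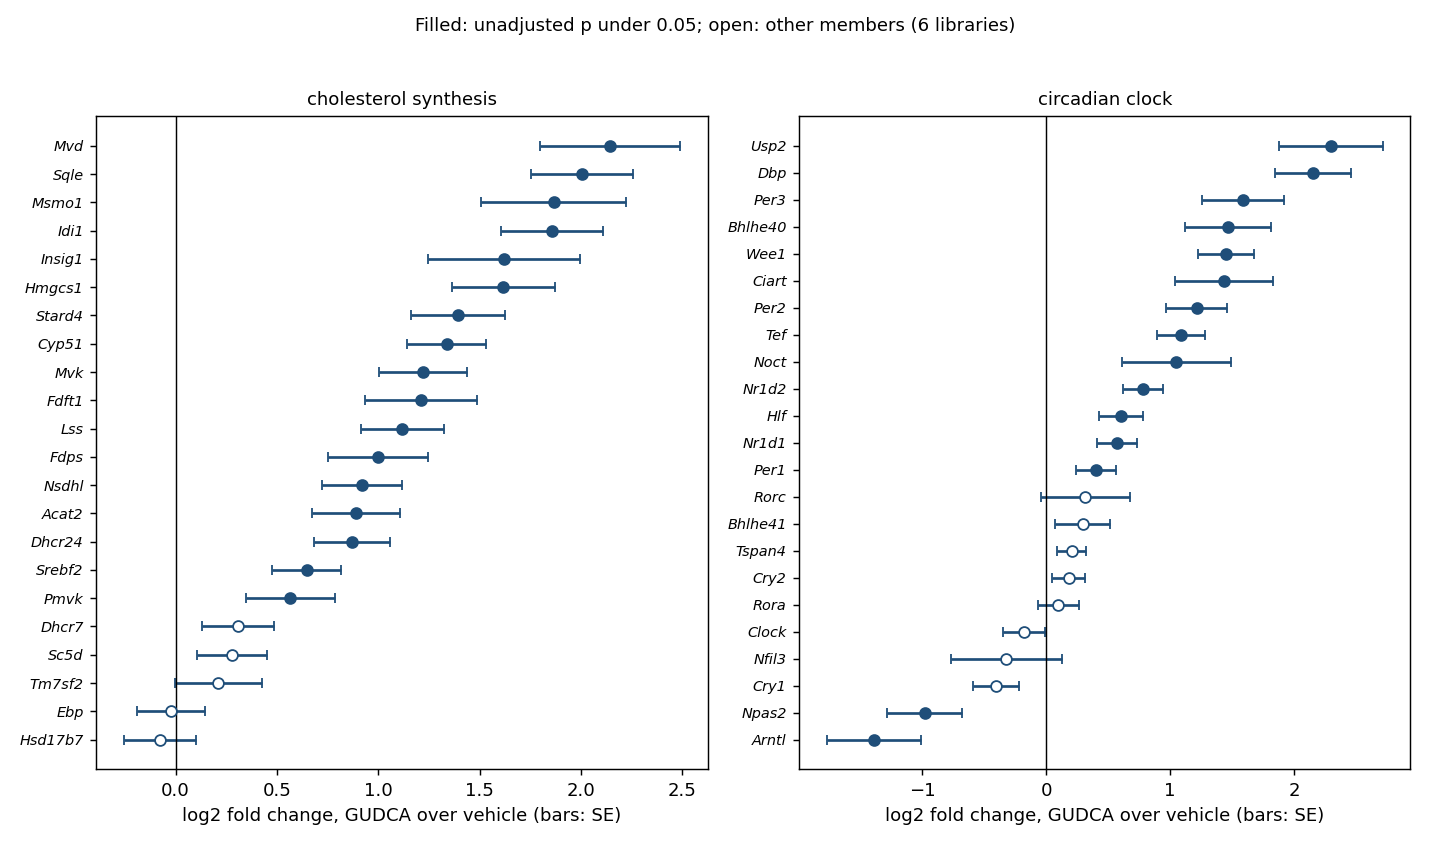
Log2 fold change (GUDCA over vehicle, 6 libraries) of most measured members of the cholesterol synthesis list and of all measured members of the circadian clock list, with SE as bars and filled points where the unadjusted p was under 0.05. Sqle and Idi1 had the smallest p in cholesterol synthesis, and Arntl, at -1.39, was the lowest clock gene.

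Genes of glucose output went in both directions. The list of gluconeogenesis and glycogen was not called (21 members, median -0.14, mean 0.0038, camera adjusted p = 0.227), and its median and mean differed in sign. For change in either direction, fry called it (adjusted p = 0.0225). There, 2 members rose, 5 fell and 14 did not pass adjusted over the list alone, and without vehicle replicate 1 the balance turned, with 8 that rose and 6 that fell. Among those that fell, G6pc, the catalytic subunit of glucose-6-phosphatase, was at -1.47 ± 0.30 (SE), with 167 ± 32.5 in GUDCA and 484 ± 181 in vehicle livers (SD, n = 3 each). The coactivator gene Ppargc1a was at -1.14 and passed over all genes without vehicle replicate 1, at -1.47 (adjusted p = 0.0263). The glycogen-targeting subunits split, with Ppp1r3b at 1.21 (adjusted p = 0.0294) and Ppp1r3g at -2.65 (adjusted p = 0.0229) without that library. With 6 libraries Ppp1r3b was at 0.89 (adjusted p = 0.327) and Ppp1r3g at -2.13 (adjusted p = 0.232). Insulin signalling was not called by camera (22 members, adjusted p = 0.783), and its median of -0.051 and its mean of 0.16 differed in sign. It was called by fry for change in either direction (adjusted p = 0.0186). Pik3r1, a regulatory subunit of PI3 kinase, was at 1.08 and the only member that rose adjusted over the list alone, and Trib3, an inhibitor of AKT, was at -0.62. In insulin signalling, 1 member rose and 1 fell without vehicle replicate 1, where the median was -0.031.

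Genes of fatty acid oxidation and PPAR alpha targets were called lower, with a median of -0.27 over 34 members (camera adjusted p = 8.44e-05, and adjusted p = 0.497 with an estimated correlation), of which 30 were below 0. None passed adjusted over the list alone, where 2 had an unadjusted p under 0.05, Fgf21 at -1.75 ± 0.59 (SE) and Angptl4 at -0.38 ± 0.16. Angptl4 was at -0.24 without vehicle replicate 1, and the list median was -0.14 without GUDCA replicate 5. The median deviation of the members from their mean over all libraries was -0.089, 0.17 and 0.25 in vehicle replicates 1, 2 and 3. It was 0.13 in GUDCA replicate 4, above vehicle replicate 1, and -0.29 and -0.23 in GUDCA replicates 5 and 6. Lipid droplet and PPAR gamma targets were called lower at a median of -0.14 over 18 members (adjusted p = 0.0346, and adjusted p = 0.456 with an estimated correlation). The droplet coat gene Plin2 was at -1.02 and the lipase inhibitor gene G0s2 at -2.05 (-1.36 without GUDCA replicate 5), and 0 members passed adjusted over the list alone, with 2 at an unadjusted p under 0.05. That call was lost without vehicle replicate 3 (median -0.11, adjusted p = 0.28) or GUDCA replicate 5 (median -0.13, adjusted p = 0.093), and without vehicle replicate 1 the median was -0.21 and 2 members fell adjusted over the list alone. Urea cycle and amino acid catabolism was called lower with 6 libraries (28 members, median -0.31, adjusted p = 0.0004, and adjusted p = 0.443 with an estimated correlation) and not without vehicle replicate 1 (median -0.22, adjusted p = 0.325), which lay 0.28 above the other vehicle libraries. Got1 was at -1.28 and the ornithine transporter gene Slc25a15 at -0.51, and 0 members passed adjusted over the list alone, with 9 at an unadjusted p under 0.05, while 2 rose and 4 fell without vehicle replicate 1.

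The bile acid genes did not pass as lists. Bile acid synthesis had a median of -0.16 over 15 members (adjusted p = 0.0781), the list of FXR (the bile acid receptor) pathway and targets -0.092 over 17 (adjusted p = 0.064) and bile acid and sterol transport 0.099 over 16 (adjusted p = 0.169). These medians depended on vehicle replicate 1, and were -0.039, 0.067 and 0.19 without it (adjusted p = 0.61, 0.372 and 0.113). The FXR list also holds Cyp8b1 and Cyp7a1, with 6 members above 0 and 11 below, and its median is no measure of receptor activity. Cyp8b1, the sterol 12-alpha-hydroxylase, averaged 456 ± 211 in GUDCA and 1041 ± 167 in vehicle livers (SD, n = 3 each), a log2 fold change of -1.27 ± 0.31 (SE, adjusted p = 0.265), and it was the only bile acid synthesis gene that fell adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, averaged 56.4 ± 18.4 and 95.3 ± 11.8, or -0.79 ± 0.22 (adjusted p = 0.311). The groups did not overlap for either gene. Cyp27a1 was at -0.13 ± 0.13 (-0.035 without vehicle replicate 1) and Cyp7b1 at -0.75 ± 0.70, Nr0b2, which encodes the repressor SHP, at 0.29 ± 0.36 and the bile salt export pump gene Abcb11 at 0.10 ± 0.22. Cyp7b1, Nr0b2 and Abcb11 changed sign with single libraries left out. Nr0b2 was at -0.14 without vehicle replicate 3, 0.63 without vehicle replicate 1, 0.16 without GUDCA replicate 5 and 0.45 without GUDCA replicate 6. Abcb11 was at -0.065 without vehicle replicate 3, -0.075 without GUDCA replicate 5, 0.27 without vehicle replicate 1 and 0.26 without GUDCA replicate 4. Cyp7b1 was at 0.19 without GUDCA replicate 6, -1.24 and -1.21 without GUDCA replicates 4 and 5, and -0.49 without vehicle replicate 2. Of the transporters, the phospholipid floppase gene Abcb4 was at -0.53 and the uptake carrier gene Slco1b2 at 0.40, and no member of the transport or FXR list passed adjusted over the list alone, with 2 and 6 members at an unadjusted p under 0.05. The counts depended on the same library, without which 1 transport member and 4 FXR members fell, and 2 bile acid synthesis members rose and 2 fell.

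Interferon response genes were called higher as a list in GUDCA livers, but the libraries of the groups overlapped. The median of 31 members was 0.61 (camera adjusted p = 1.23e-10, and adjusted p = 0.409 with an estimated correlation), and 30 were above 0, of which 2 passed adjusted over the list alone, while 0 fell and 29 did not pass. Usp18, which limits interferon signalling, was at 1.33 ± 0.20 (SE) and Oasl2 at 1.25 ± 0.30. The median deviation of the members from their mean over all libraries was 0.59 and 0.45 in GUDCA replicates 4 and 6. In GUDCA replicate 5 it was 0.0019, below vehicle replicate 1 at 0.028, with vehicle replicates 2 and 3 at -0.27 and -0.67. Vehicle replicate 1 lay 0.51 above the other vehicle libraries in this list, and without it the median was 0.75, with 18 members passing adjusted over the list alone and Usp18 over all genes. Inflammation and chemokines was called higher at a median of 0.57 over 21 members (adjusted p = 3.09e-05, and adjusted p = 0.409 with an estimated correlation), and 2 rose adjusted over the list alone, Tnfaip3 at 1.19 ± 0.25 and Ccl5 at 1.49 ± 0.35. Vehicle replicate 1 lay 0.40 below the other vehicle libraries there (-0.40), and without it the median was 0.32 (adjusted p = 0.00295, and adjusted p = 0.583 with an estimated correlation) and 4 members rose. The acute phase response was not called by camera (26 members, adjusted p = 0.906), and its median of -0.066 and mean of 0.28 differed in sign. It was called by fry for change in either direction (adjusted p = 0.0186). Saa3 and the metalloreductase gene Steap4, at 1.53, rose adjusted over the list alone, and without vehicle replicate 1 the median was -0.19, the direction of the test turned to lower (adjusted p = 0.509), and 4 members rose and 1 fell.

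Fibrosis and extracellular matrix genes were higher in GUDCA livers, with a median of 0.72 over 26 members (camera adjusted p = 3.62e-13, and adjusted p = 0.409 with an estimated correlation). Adjusted over the list alone, 11 rose, 0 fell and 15 did not pass. Col1a2 averaged 31.9 ± 2.35 and 14.1 ± 2.28 normalized read counts (SD, n = 3 each), Col3a1 50.0 ± 11.3 and 23.4 ± 1.41, and Thbs1 6.30 ± 1.42 and 1.38 ± 0.36. Stellate cell markers, several of which are also matrix genes, had a median of 0.64 over 17 members (adjusted p = 1.63e-07, and adjusted p = 0.409 with an estimated correlation). All 17 were above 0 and 3 rose adjusted over the list alone, Col3a1 and Col1a1 at 1.04 and 1.01 among them. Vehicle replicate 1, the library with low endothelial and Kupffer cell markers described below, was low in both lists, at -0.73 and -0.66 against the other vehicle libraries. Without it the medians were 0.47 (adjusted p = 3.11e-08) and 0.33 (adjusted p = 0.000149), each with an adjusted p = 0.511 with an estimated correlation, and Col1a2 and Thbs1 passed over all genes.

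Glucocorticoid, heat shock and immediate early genes were called higher, with a median of 0.71 over 31 members (camera adjusted p = 7.34e-10, and adjusted p = 0.356 with an estimated correlation). Adjusted over the list alone 7 rose (13 without vehicle replicate 1) and 24 did not pass, the growth arrest gene Gadd45a at 1.78 and the immediate early gene Egr1 at 1.82 among those that rose, with Fos at 8.82 ± 3.05 in GUDCA and 2.46 ± 0.86 in vehicle livers (SD, n = 3 each). Proliferation genes were called at a median of 0.33 over 19 members (adjusted p = 0.00135, and adjusted p = 0.356 with an estimated correlation), with Mcm6 at 0.67 and Top2a at 0.74, and 0 passed adjusted over the list alone, where 4 had an unadjusted p under 0.05 and 2 rose without vehicle replicate 1. Drug metabolism genes had a median of 0.12 over 26 members (adjusted p = 0.0329, and adjusted p = 0.643 with an estimated correlation), a call lost without vehicle replicate 2 (median 0.16, adjusted p = 0.095), vehicle replicate 3 (0.068, adjusted p = 0.55) or GUDCA replicate 6 (0.19, adjusted p = 0.21). The median was 0.30 without vehicle replicate 1, which lay 0.47 above the other vehicle libraries, and 0.21 without GUDCA replicate 5. Gstm3 and Gstm2 were at 1.63 and 0.69, and 0 members passed adjusted over the list alone, with 4 at an unadjusted p under 0.05, while 5 rose without vehicle replicate 1. Gstm3 shares 43.2% of its transcript with a near-identical gene.

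The proteasome list was called lower, at a median of -0.22 over 30 members (camera adjusted p = 1.63e-07, and adjusted p = 0.472 with an estimated correlation), with 29 below 0, and at -0.38 without GUDCA replicate 4. Psmd6 was at -0.38 and Psmc4 at -0.48, and 0 passed adjusted over the list alone, with 4 at an unadjusted p under 0.05. The groups overlapped, with GUDCA replicate 4 at a median deviation of 0.13 and vehicle replicates 1, 2 and 3 at 0.036, 0.062 and 0.28. GUDCA replicates 5 and 6 were at -0.23 and -0.28. ER stress and unfolded protein response had a median of -0.21 over 30 members (adjusted p = 0.0248, and adjusted p = 0.66 with an estimated correlation), and 0 passed adjusted over the list alone, with 6 at an unadjusted p under 0.05. Its call was lost without vehicle replicate 1 (-0.056, adjusted p = 0.325), vehicle replicate 2 (-0.10, adjusted p = 0.18), GUDCA replicate 4 (-0.18, adjusted p = 0.079) or GUDCA replicate 6 (-0.075, adjusted p = 0.22), and its median was -0.35 without vehicle replicate 3 and -0.31 without GUDCA replicate 5. Vehicle replicate 1 lay 0.26 above the other vehicle libraries in it, and without it 1 member rose adjusted over the list alone. The stress transcription factor gene Atf4 was at -0.58 ± 0.17 (SE), its target Trib3 at -0.62 ± 0.18, the chaperone gene Hspa5 at -0.42 ± 0.23 (adjusted p = 0.56, with -0.66 without vehicle replicate 3 and -0.27 without GUDCA replicate 6) and Ddit3, the gene of CHOP, at -0.54 ± 0.20 (adjusted p = 0.404). The integrated stress response list was not called (20 members, median -0.069 and -0.11 without vehicle replicate 1, adjusted p = 0.198), and 0 members passed adjusted over the list alone, with 5 at an unadjusted p under 0.05. Nuclear genes of oxidative phosphorylation were called lower at a median of -0.12 over 36 members (adjusted p = 0.0039, and adjusted p = 0.72 with an estimated correlation), with Cox5a at -0.26 and Uqcrc1 at -0.22 (-0.12 and -0.11 without vehicle replicate 1), and 0 members reached an unadjusted p under 0.05. That call was lost without vehicle replicate 1 (0.0039, adjusted p = 0.878), which lay 0.43 above the other vehicle libraries, or GUDCA replicate 6 (-0.054, adjusted p = 0.13), and the median was -0.21 without vehicle replicate 3.

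Markers of endothelial cells, macrophages and several other non-parenchymal cells were low in vehicle replicate 1. Against the other vehicle libraries its median marker level was -2.90 on the log2 scale for endothelial cells, -1.71 for macrophages and Kupffer cells and -0.91 for neutrophils, and 0.35 for hepatocytes and 0.16 for cholangiocytes. Kdr, an endothelial receptor gene, was at 2.99 normalized read counts in vehicle replicate 1 and between 22.1 and 67.9 in the other libraries, and the Kupffer cell gene Clec4f at 64.4 and between 186 and 324. With 6 libraries, endothelial markers were called higher in GUDCA (19 members, median 0.68, camera adjusted p = 0.00661, and adjusted p = 0.67 with an estimated correlation), but without vehicle replicate 1 they were at -0.24 (adjusted p = 0.113). The median was 1.27 without vehicle replicate 2 and 1.20 without vehicle replicate 3, and without GUDCA replicate 6 the call was lost at 0.53 (adjusted p = 0.072). Macrophage and Kupffer cell markers were at 0.74 over 18 members (adjusted p = 1.35e-05, and adjusted p = 0.497 with an estimated correlation) and at 0.20 without vehicle replicate 1 (adjusted p = 0.0733). In these lists 0 members passed adjusted over the list alone, with 1 each at an unadjusted p under 0.05, Lyve1 at 1.87 and Marco at 1.22. The endothelial gene Eng was at 0.49 and the macrophage gene Cd68 at 1.14. Without vehicle replicate 1, Lyve1 was at 0.94, Eng at 0.083 and Cd68 at 0.46.

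**Figure D4:**
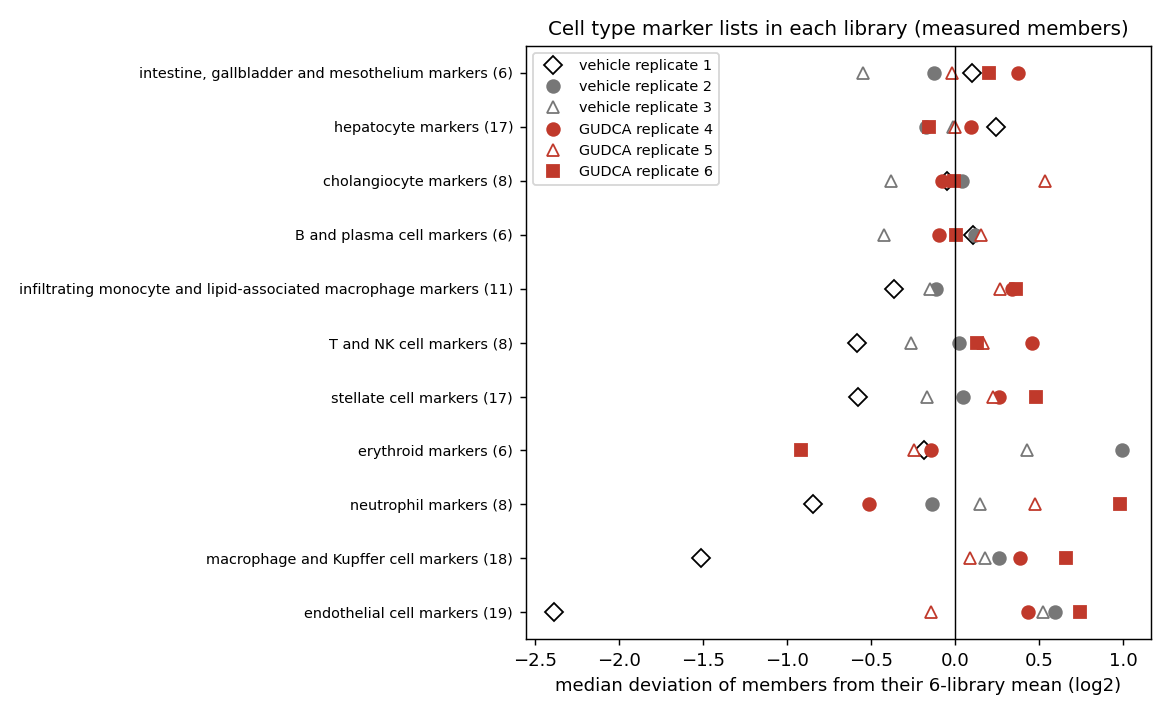
Median deviation (log2) of the measured members of each cell type marker list from their mean over the 6 libraries, with 1 symbol per library. Vehicle replicate 1 (open diamonds) lies far to the left for endothelial and for macrophage and Kupffer cell markers, where it was at -2.90 and -1.71 against the other vehicle libraries.

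Immune markers were also called higher, in part through that library. Markers of infiltrating monocytes and lipid-associated macrophages had a median of 0.57 over 11 members (camera adjusted p = 0.000541, and adjusted p = 0.356 with an estimated correlation), with S100a6 at 1.29 ± 0.32 (SE) and Lgals3 at 0.95 ± 0.28 (0.63 without vehicle replicate 1), and 2 rose adjusted over the list alone. Vehicle replicate 1 was at -0.30 there, and the median was 0.45 (adjusted p = 0.00234, and adjusted p = 0.511 with an estimated correlation, with 4 members that rose) without it and 0.38 without vehicle replicate 2. T and NK cell markers were at 0.50 over 8 members (adjusted p = 0.0039, and adjusted p = 0.409 with an estimated correlation), with Ccl5 at 1.49 and Gzmb at 0.78, and 1 rose adjusted over the list alone. Gzmb averaged only 2.43 in GUDCA and 0.977 in vehicle livers. Without vehicle replicate 1, which was at -0.34, the call of this list was lost (0.37, adjusted p = 0.0533). Neutrophil markers were at 0.76 over 8 members (adjusted p = 0.00477, and adjusted p = 0.497 with an estimated correlation), with Mmp9 at 0.89 and Cxcr2 at 0.80. Mmp9 averaged only 2.44 in GUDCA and 0.836 in vehicle livers, and Cxcr2 only 1.90 and 0.613. The neutrophil call was lost without vehicle replicate 1 (0.34, adjusted p = 0.14), GUDCA replicate 5 (0.43, adjusted p = 0.071) or GUDCA replicate 6 (0.27, adjusted p = 0.21). Class II antigen presentation was at 0.20 over 10 members (adjusted p = 0.0302, and adjusted p = 0.409 with an estimated correlation), with Ctss at 0.99 (0.30 without vehicle replicate 1) and H2-Ab1 at 0.27 (0.15 without vehicle replicate 3), and its call was lost without vehicle replicate 1 (0.20, adjusted p = 0.114), vehicle replicate 3 (0.14, adjusted p = 0.069) or GUDCA replicate 5 (0.15, adjusted p = 0.095). Vehicle replicate 1 was at -0.15 there. Erythroid markers were called lower, at -0.89 over 6 members (adjusted p = 0.00386, and adjusted p = 0.443 with an estimated correlation). The globin gene Hbb-bs was at -1.15 (-1.69 without vehicle replicate 1 and -0.67 without vehicle replicate 2) and Bpgm at -0.43. Of the Hbb-bt transcript, 55.9% is near-identical to Hbb-bs, so the value of Hbb-bs is uncertain too. The erythroid median was -1.18 without vehicle replicate 1, which was at -0.86 against the other vehicle libraries, and -0.55 without GUDCA replicate 6. In the neutrophil, class II and erythroid lists 0 members passed adjusted over the list alone, with 1, 0 and 3 at an unadjusted p under 0.05. Of the erythroid members, 4 fell adjusted over the list alone and 1 over all genes without vehicle replicate 1, while the neutrophil and class II counts stayed at 0.

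Hepatocyte identity genes showed no call, and the signs of most medians here rested on vehicle replicate 1. Hepatocyte markers were at -0.0062 over 17 members (camera adjusted p = 0.906), with a mean of 0.0098 that differed in sign, and Hnf4a was at 0.41 (0.22 without vehicle replicate 1 and 0.66 without vehicle replicate 3) and Cps1 at -0.45 (-0.23 without vehicle replicate 3). Periportal markers were at -0.078 over 17 (adjusted p = 0.207), with the arginase gene Arg1 at -0.50 and Pck1 at -0.46. Pericentral markers were at 0.072 over 18 (adjusted p = 0.926), with a mean of -0.0014 that differed in sign, and Cyp7a1 was at -0.79 and the Wnt target Axin2 at -0.60 (-0.38 without vehicle replicate 3). Growth hormone and sex-biased genes were at -0.19 over 25 (adjusted p = 0.378), where Mup1 was at -1.44 and Mup7 at -1.09 (-0.61 without GUDCA replicate 6), again with near-identical copies. Complement and coagulation stood at -0.029 over 29 members (adjusted p = 0.399), with C1qa, made by macrophages, at 0.80 (0.33 without vehicle replicate 1). Cytosolic ribosomal proteins stood at -0.033 over 42 (adjusted p = 0.522), with Rpl22 at 0.11 and Rplp0 at -0.10, and mitochondrial genome transcripts at -0.12 over 12 (adjusted p = 0.378), with mt-Nd5 at -0.33 and mt-Nd6 at -0.30. With each library left out in turn, Rpl22 ran from 0.055 (without vehicle replicate 2) to 0.21 (without vehicle replicate 1). Without GUDCA replicate 6, Rplp0 was at -0.033, mt-Nd5 at -0.15 and mt-Nd6 at -0.072, and mt-Nd6 was at -0.47 without vehicle replicate 3. Of the longest Rplp0 transcript, 70.25% is near-identical to other genes, so its value is uncertain. With vehicle replicate 1 left out, the medians were 0.11 for hepatocyte, 0.065 for periportal and 0.19 for pericentral markers, 0.014 for growth hormone and sex-biased genes, 0.091 for complement and coagulation, 0.076 for ribosomal proteins and 0.068 for mitochondrial transcripts, and none of these lists was called. No member of these lists passed adjusted over the list alone, and without vehicle replicate 1 only 1 periportal member did, which rose.

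Stress and minor cell lists gave no call by camera either. For change in either direction, fry called apoptosis and p53 targets (adjusted p = 0.0225) and intestine, gallbladder and mesothelium markers (adjusted p = 0.0422). Antioxidant NRF2 targets were at -0.11 over 25 members (adjusted p = 0.169), with Gpx1 at -0.52 and Gstm3 at 1.63, and the hypoxia response at 0.13 over 14 (adjusted p = 0.749), with Epas1 at 0.65 and Ndrg1 at 0.63. In both, 0 members passed adjusted over the list alone, with 4 and 5 at an unadjusted p under 0.05. Among NRF2 targets 2 rose and 1 fell without vehicle replicate 1, and 1 hypoxia gene fell, with medians of -0.067 and 0.023. Apoptosis and p53 targets were at 0.15 over 22 members (adjusted p = 0.0596), where the stress gene Trp53inp1, at 1.92, rose adjusted over the list alone and the survival gene Mcl1 was at 0.51. Markers of intestine, gallbladder and mesothelium were at 0.19 over 6 (adjusted p = 0.169). Adjusted over the list alone, the mesothelial genes Msln and Upk3b rose, at 1.74 and 1.08, and Fabp2 fell by 0.59. However, Msln averaged only 3.07 in GUDCA and 0.124 in vehicle livers, and Upk3b only 1.77 and 0.309. Cholangiocyte markers were at 0.24 over 8 (adjusted p = 0.186), with Krt19 at 0.58 (0.31 without vehicle replicate 3) and Pkhd1 at 0.43 (0.28 without GUDCA replicate 5), and B and plasma cell markers at 0.11 over 6 (adjusted p = 0.641), with Cd22 at 0.74 (0.25 without vehicle replicate 1) and Ighm at -0.22 (-0.067 without GUDCA replicate 5 and -0.37 without GUDCA replicate 4). Leaving out vehicle replicate 1 moved the medians to 0.39 for cholangiocyte, 0.18 for B and plasma cell and 0.34 for intestine, gallbladder and mesothelium markers, still without a call. In the cholangiocyte and B cell lists 0 members reached an unadjusted p under 0.05. Platelet, adipocyte, pancreas and muscle markers had 3, 4, 1 and 0 measured members and were not tested.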

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

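The DESeq2 fit, the edgeR fit with the first vehicle library left out and the endothelial covariate were chosen after seeing the data. The count of 0 changed genes held under a pseudocount of 0.1, a stricter filter, median-ratio scaling, quantile normalization, no variance trend and edgeR on 6 libraries. Without a filter 2 genes were called, both higher. Weights per library gave 741 genes (368 higher, 373 lower), with a weight of 5.28 for vehicle replicate 2 and 0.273 for vehicle replicate 1. The endothelial covariate gave 94 (68 and 26), edgeR with the first vehicle library left out 51 (34 and 17) and DESeq2 189 (116 and 73). Leaving out each library in turn gave 0 to 55 genes, with 0 to 40 higher and 0 to 15 lower. The list count fell from 23 to 15 with weights per library and to 0 with an estimated correlation or with fry, and ran from 15 to 24 with each library left out. Of the 23 called lists, 13 were called in each fit that left out 1 library. The endothelial list turned from 0.68 to -0.23 with weights per library and to -0.074 with its own mean as a covariate, which removes it by construction, and ran from -0.24 to 1.27 with each library left out. Oxidative phosphorylation ran from -0.21 to 0.0039, Nr0b2 from -0.14 to 0.63, Abcb11 from -0.075 to 0.27 and Cyp7b1 from -1.24 to 0.19. Of the other values of single genes, 1485 kept their direction and side of the threshold and 171 came to pass it, while for lists 280 kept both and 81 lost the call. The cause of these differences was not tested. The median of all genes was 0.0037 under median-ratio scaling and -0.021 under quantile normalization. No paired analysis was possible because the replicate numbers of the groups do not repeat. The count test planned for deposited raw counts, edgeR, was run on the recovered reads instead, as the files hold normalized values. At 3 libraries per group, changes near 1 on the log2 scale were recovered for 49.1% of simulated genes. The simulated libraries varied independently gene by gene, so that share does not carry over to data with a library such as vehicle replicate 1.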

Other observations

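Of the tests below, those of depth, of less RNA of non-parenchymal cells, of time of day, of feeding and of vehicle replicate 1 for the cholesterol list were chosen only after the result was seen. The bootstrap spread was made part of the bounds when the medians without vehicle replicate 1 were already known, and was tightened after a first look at the outcomes. That change moved the fibrosis list (0.47 ± 0.11) from against its explanation to undecided, and the time of day (-0.40 ± 0.34) from in favour to undecided. The fibrosis list and the fasting genes (-0.47 ± 0.15) lie near their bounds, so those outcomes are weak.

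Beyond the lists, further genes among the 55 that passed without vehicle replicate 1 are named here after their values were seen. The uridine phosphorylase gene Upp2 rose by 2.06 ± 0.17 (SE, adjusted p = 0.00465) and Hamp2, of the hepcidin family, by 2.65 ± 0.36 (adjusted p = 0.0313). The corticosteroid-binding globulin gene Serpina6 rose by 1.70 ± 0.24 (adjusted p = 0.0321) and the carboxylesterase gene Ces1f by 1.70 ± 0.24 (adjusted p = 0.0321). Cntnap1 fell by 2.54 ± 0.39 (adjusted p = 0.044) and the globin gene Hbb-bt by 1.58 ± 0.23 (adjusted p = 0.0374). With 6 libraries these genes did not pass and were at 1.66 for Upp2 (adjusted p = 0.19), 1.75 for Hamp2 (0.43), 1.24 for Serpina6 (0.343), 1.21 for Ces1f (0.359), -1.67 for Cntnap1 (0.447) and -1.01 for Hbb-bt (0.479). Of the Hbb-bt transcript, 55.9% is near-identical to Hbb-bs, so its value is uncertain.

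Vehicle replicate 1 differed from the other vehicle libraries in markers of endothelial cells (-2.90) and of macrophages and Kupffer cells (-1.71). A difference in depth or scaling would move all lists alike, but its hepatocyte median lay 3.25 ± 0.30 (bootstrap SD) above its endothelial median. Removing the trend with GC content and transcript length, which explained 6.37% of the variance between genes, left the endothelial median at -2.78 ± 0.30, so that trend is not the whole source. Less RNA of non-parenchymal cells in that sample may account for the pattern, but the stellate markers, at -0.66 ± 0.32, fell between the bounds set for and against it, and the cholangiocyte markers were at 0.16. Transcripts of the ribosomal locus made up 0.824% of its values and 0.325% to 0.404% elsewhere, and how the tissue piece or its RNA differed is not given in the labels.

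The lists of non-parenchymal cells and inflammation were called higher in GUDCA, and vehicle replicate 1 alone is a candidate source. For endothelial and macrophage markers the call rested on it, as without it the medians were -0.24 ± 0.080 (bootstrap SD) and 0.20 ± 0.033 and neither list was called, although the macrophage median stayed above 0. This spread leaves out differences between libraries. Camera with an estimated correlation gave these lists an adjusted p of 0.819 and 0.775 without that library. The interferon response argues against vehicle replicate 1 alone, with a median of 0.75 ± 0.085 without that library and 0.61 with it. For stellate markers (0.33 ± 0.092), fibrosis and matrix (0.47 ± 0.11) and inflammation (0.32 ± 0.19) the lists were still called without it at the preset correlation, though not with an estimated correlation (adjusted p = 0.511, 0.511 and 0.583), and their medians lay within their spread of 50 percent of the 6-library value, so a share from that library and a difference between the groups cannot be told apart. An effect of GUDCA on these genes stays open and was not tested separately.

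Cholesterol synthesis genes and clock genes differed between the groups, and for the cholesterol genes vehicle replicate 1 or the scaling between libraries does not account for this, as their median was 1.22 ± 0.22 (bootstrap SD) without that library and at least 1.11 ± 0.19 under median-ratio scaling and quantile normalization. A more recent meal before collection in the GUDCA mice is a candidate explanation, since the 12 measured fasting-induced genes were all below 0 with a median of -0.47 ± 0.15, Ppargc1a, Fgf21 and G6pc among them. Another time of day or clock phase at collection might also apply. Clock genes that peak late in the light phase had a median of 0.94 with 10 of 10 above 0. Those in antiphase had a median of -0.40 ± 0.34 with 5 of 5 below 0, Npas2 with its low values among them, but their spread left this undecided. Whether feeding or time of collection differed between the groups is not given in the labels, and an effect of the bile acid on these genes stays open as well. Feeding times and hours of collection would be needed to separate them.

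Chance in the grouping could be weighed only in part, because 3 against 3 libraries make 10 splits and no share under 0.1 can arise. The real split gave 1491 genes at an unadjusted p under 0.05, and the highest other split gave 1411, so 1 of 10 splits reached the real count. That other split set vehicle replicate 1 and GUDCA replicates 5 and 6 against the rest, so it kept 4 of the 6 libraries on their real sides. No test here separates a weakened difference between the groups from another structure of the samples. For lists the real split gave 23 and the highest other 22, again 1 of 10 reaching the real count, and for genes at an adjusted p of 0.05 all 10 splits gave 0 by limma. The cholesterol list had 20 members at an unadjusted p under 0.05 in the real split and at most 13 in another. It also had the smallest camera p in the real split, and no other list was followed across splits. That comparison therefore does not weigh against chance.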
